A study of Mus musculus with 12 samples.

How the data were processed

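RNA was measured by sequencing in 12 libraries of primary mouse stomach epithelial cells, 2 libraries in each of 6 groups. The 3 genotypes TY, TP and TPCD were each treated with DMSO or with rapamycin at 10 nM for 24 hours, per the labels' protocols. RNA was extracted with TRIzol, captured by poly-A, made into stranded libraries and sequenced as paired reads, per the labels' protocols. The labels do not say whether the replicates of a group came from separate cultures or animals, so every p-value here measures the spread between these libraries and nothing wider.

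The deposited table holds a library-size scaled signal for 31053 genes. Salmon 1.10.0, DESeq2 1.46.0 and the builds mm10 and GRCm38 are named without role or order, per the submitters' processing notes. The counting step, the annotation, the strand setting and any filter are not stated there. In the deposited table all 12 columns summed to 34662604, and each column's values were whole multiples of 1 step, within a tolerance of 0.01 reads for 100% of values. Dividing by the step gave back whole reads, 34637260 to 40597448 per library. For the first rapamycin replicate of TY the step was 1.00073, which lies near 1, so its recovery rests on the decimals of the deposited signal. 7580 genes were at 0 in all libraries. Of the gene identifiers, 30934 were matched to a symbol (99.6%) and 119 were not. Coordinates were taken from the GENCODE annotation of GRCm38 (mm10), counted from 1. No column was left out.

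The scaled signal is not a count, so the test fixed for normalized values was used, as set before the data were examined. It was limma 3.58.1 with an intensity trend and robust moderation on log2(signal + 1), in R 4.3.3 with statmod 1.5.0. Genes with a signal of at least 10 in at least 2 libraries were tested, which left 15712. All 6 groups were fitted in one group-means model. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with calls at 0.05 and no fold minimum. A log2 change given with SE comes from this model, and a value given with ± is the mean and SD of the deposited signal over n = 2 libraries. Comparisons were made between genotypes in DMSO and in rapamycin, between rapamycin and DMSO within each genotype, and between the rapamycin responses as interaction terms.

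33 gene lists were fixed before the data were examined: gastric pit (foveolar) cell, mucous neck and SPEM, chief cell, parietal cell, enteroendocrine cell, tuft cell, Wnt target and stem cell, intestinal metaplasia, squamous and forestomach, epithelial identity, mesenchymal transition, fibroblast (other cell type), immune (other cell type), endothelial (other cell type), FOXO target, cholesterol synthesis, fatty acid synthesis, ATF4 and amino acid, glycolysis and HIF, ribosome biogenesis, lysosome and TFEB target, mTOR pathway component, G2 and M phase, S phase and replication, interferon response, antigen presentation, NF-kB and chemokine, p53 target, YAP target, ERK feedback and immediate early, NRF2 target, unfolded protein response, H3K4 methylation machinery. Each was tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and adjusted over the lists within a comparison. The 32 lists with at least 5 tested members had this set test. Camera was run beside it with an estimated correlation, and counts of members were also adjusted over the list alone. A set test is called at an adjusted p under 0.05 at the preset correlation.

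Named genes followed a rule. In each main comparison these were the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap between the groups and whose mean lay above the median of the genes tested. Gene models, pseudogenes and the sex-specific genes Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty were left out of that choice. Other X-linked genes stayed in it. The rule also took the 3 most changed passing members of each called list, the 6 largest interaction terms in each direction, and Pten, Kmt2c and Kmt2d. Where all libraries of a group were at 0, a fold is given as at least the ratio to 3 reads per library. Where a group had few reads, the ratio of reads is given with its 95% exact conditional binomial interval. These intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

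The rapamycin responses of the genotypes were compared by the number of shared calls against the number expected from their sizes. The genotype difference in rapamycin was regressed on that in DMSO across genes, which are not independent replicates. Because a genotype difference and a rapamycin response share libraries, their covariance was set beside that of 50 simulated unchanged groups that shared them alike, a comparison added after the data were seen. Chromosome medians used 11062 autosomal genes with a mean signal of at least 100.

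The tests were tried on simulated counts drawn from the real means and library sizes. In these draws all groups shared the same mean per gene, apart from the genes changed in a single group. The rates therefore do not cover comparisons in which most genes differ or the scaling shifts. For TPCD against TP in DMSO, limma recovered 85.1% of 67 genes changed 1.5-fold, 98.5% of 67 genes changed 2-fold and 100% of 66 genes changed 4-fold, with 10 false among 199 calls over 14949 genes. For rapamycin in TPCD it recovered 83.6%, 95.5% and 98.5% at those sizes, with 8 false of 193 calls over 14959 genes. For the difference of the responses of TPCD and TP it recovered 71.6%, 83.6% and 100%, with 13 false of 183 calls over 14954 genes.

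Alternatives were TMM (edgeR 4.0.16), DESeq2 1.42.0 size factors and upper-quartile scaling, no filter or a stricter filter on low values, pseudocounts of 0.5 and 5, only the groups compared, the replicate number as a block, a minimum of 2-fold and leaving out each library in turn. DESeq2 and limma-voom were run on the recovered reads, and edgeR's quasi-likelihood test on these reads was added after the data were seen. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.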

Results

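RNA from primary stomach epithelial cells of mice was sequenced to compare the transcriptomes of 3 genotypes with and without rapamycin, an inhibitor of mTOR complex 1. TY cells served as the control and carry a tamoxifen-inducible Cre under Tmprss2 with a fluorescent reporter. TP cells carry floxed Pten, which encodes the phosphatase that opposes PI3K. TPCD cells carry floxed Pten, Kmt2c and Kmt2d, the latter pair encoding H3K4 methyltransferases. Each genotype was treated with DMSO or with 10 nM rapamycin for 24 hours, with 2 libraries per group. The libraries held 34637260 to 40597448 recovered reads. The genes above 0 numbered 19286 ± 46.7 in TP DMSO and between 17594 ± 18.4 (TY rapamycin) and 18076 ± 149 (TP rapamycin) in the other groups. Mitochondrial transcripts took 1.84% of the signal in TY DMSO, 2.57% in TP DMSO and 2.43% in TPCD DMSO, and 2.20%, 3.58% and 3.06% with rapamycin. Replicates correlated across genes with r of 0.993 to 0.994, and the first principal components took 56.5% and 32.7% of the variance.

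The targeted genes were examined first. Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160) had a signal of 5511 ± 216 in TY DMSO, 2847 ± 59.0 in TP DMSO and 2414 ± 9.49 in TPCD DMSO, and of 4783 ± 143, 3387 ± 132 and 2335 ± 94.1 with rapamycin. It fell in TP against TY in DMSO, with a log2 change of -0.95 (SE 0.05, adjusted p = 4.10e-10). Kmt2c (ENSMUSG00000038056, chromosome 5, 25271798 to 25498783) stood at 3803 ± 614, 2173 ± 212 and 575 ± 19.5 in DMSO and at 3205 ± 504, 1802 ± 135 and 720.4 ± 107 in rapamycin. It fell in TPCD against TP, with a log2 change of -1.91 (SE 0.13, adjusted p = 4.20e-08), and its log2 change in TP against TY was -0.80 (SE 0.13, adjusted p = 0.000131). Kmt2d (ENSMUSG00000048154, chromosome 15, 98831669 to 98871204) stood at 3992 ± 273, 3057 ± 371 and 2994 ± 123 in DMSO and at 3904 ± 272, 2638 ± 299 and 3859 ± 208 in rapamycin. Its log2 change in TPCD against TP was -0.03 (SE 0.09, adjusted p = 0.806) in DMSO and 0.55 (SE 0.09, adjusted p = 9.83e-05) in rapamycin, so Kmt2d was not lower in the libraries labelled TPCD than in those of TP. Values per gene may include exons outside the deleted part, so they do not check the deletions, and every direction drawn from the TPCD label below rests on that label. The values of the targeted genes were also not set against the chromosome-wide shifts given below. Under DESeq2 size factors the log2 change of Kmt2d in TPCD against TP in DMSO was 0.22 (adjusted p = 0.0297) and that of Pten 0.01 (adjusted p = 0.903, as deposited -0.24), so the direction of both turned with the scaling. Kmt2d thereby gained a call as higher in TPCD, as it did with TMM (adjusted p = 0.0245) and on the recovered reads with DESeq2 (0.0208), voom (0.0191) and edgeR (0.0172), but not with upper quartiles (0.0759), and Pten lost its call as lower. With rapamycin the log2 change of Pten was -0.20 (SE 0.05, adjusted p = 0.00865) in TY, a call lost with DESeq2 size factors (-0.12, adjusted p = 0.0903), and 0.25 (SE 0.05, adjusted p = 0.000717) in TP.

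**Figure D1:**
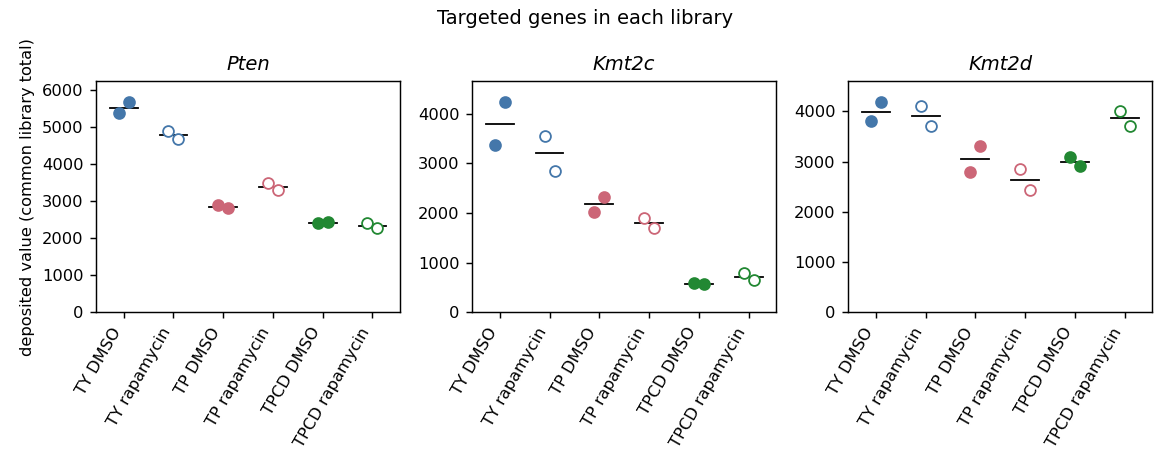
Deposited signal of Pten, Kmt2c and Kmt2d in each of the 12 libraries, with points for replicates, bars for the group mean, DMSO filled and rapamycin open. Kmt2c in the libraries labelled TPCD lay near 575 in DMSO against 3803 in TY, while Kmt2d lay at 2994 in TPCD and 3057 in TP.

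The comparison of TP with TY in DMSO asks what differs in the cells with floxed Pten. All 20 genes of epithelial identity fell (median log2 change -2.80, adjusted p = 3.68e-12, adjusted p = 0.0554 with an estimated correlation). Ap1m2, the epithelial clathrin adaptor subunit, stood at 8.43 ± 2.16 against 5544 ± 299.6, Rab25, a GTPase of epithelial recycling, at 24.2 ± 3.57 against 7144 ± 236, and the tight junction gene Cldn4 at 109 ± 21.7 against 13029 ± 700.5. Of 19 tested genes of mesenchymal transition, 15 rose, 3 fell and 1 did not pass (median log2 change 7.14, or 6.75 with members under the floor at their bound, adjusted p = 0.00396, adjusted p = 0.138 with an estimated correlation). Vimentin (Vim) reached 11989 ± 667 against 10.4 ± 0.799, the collagen crosslinker Loxl2 7381 ± 325 against 9.48 ± 0.493 and Zeb2, a repressor of E-cadherin, 4623 ± 100.2 against 9.16 ± 6.50. Markers of other cell types moved with them: all 8 tested fibroblast genes rose (median 6.32, or 5.58 at the bound, adjusted p = 0.00414, adjusted p = 0.136 with an estimated correlation), as did all 6 tested endothelial genes (median 4.83, or 4.08 at the bound, adjusted p = 0.0473, adjusted p = 0.251 with an estimated correlation). Dcn, a fibroblast proteoglycan, stood at 467 ± 13.8 and the endothelial cadherin Cdh5 at 289 ± 13.5 in TP, below the median tested gene (859). The collagen gene Col5a1, also on the fibroblast list, had 11264 reads in TP against 12 in TY. Of 12 tested genes of intestinal metaplasia 8 rose, 1 fell and 3 did not pass (median 4.90, or 4.64 at the bound, adjusted p = 0.0473, adjusted p = 0.188 with an estimated correlation). Cdx2, which sets intestinal identity, had 1 read in TY and 1724 ± 63.8 in TP, a ratio of reads of 3645-fold (95% counting interval 654 to 143993).

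Inflammatory genes were higher in TP. All 31 interferon response genes rose (median log2 change 5.22, adjusted p = 1.32e-09, adjusted p = 0.0808 with an estimated correlation), with the nucleic acid sensor Zbp1 at least 320-fold higher and Oas2 706-fold (95% counting interval 241 to 3428) higher. Of 25 NF-kB and chemokine genes, 23 rose, 2 fell and 0 did not pass (median log2 change 2.86, adjusted p = 7.31e-06, adjusted p = 0.138 with an estimated correlation). The monocyte attractant Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) was 18987-fold (95% counting interval 9636 to 43979) higher and the related chemokine Ccl7 24327-fold (95% counting interval 4366 to 960903). In antigen presentation 17 of 18 rose and 1 fell (median log2 change 2.30, adjusted p = 0.000173, adjusted p = 0.254 with an estimated correlation), or a median of 2.21 with members at their bound, with the immunoproteasome subunit Psmb8 up from 1 read, a ratio of 1708-fold (95% counting interval 306 to 67479). Of 32 ATF4 and amino acid genes, 30 rose and 2 fell (median log2 change 1.85, adjusted p = 2.45e-07, adjusted p = 0.107 with an estimated correlation). The mitochondrial folate enzyme Aldh1l2 stood at 7364 ± 235 against 192 ± 7.43 and Atf3 at 4621 ± 133 against 148 ± 30.4. Of 28 genes of glycolysis and HIF, 24 rose, 1 fell and 3 did not pass (median log2 change 1.31, adjusted p = 7.31e-06, adjusted p = 0.438 with an estimated correlation). The lactate exporter Slc16a3 stood at 18561 ± 1413 against 10.3 ± 6.16.

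Proliferation and sterol genes were lower in TP. All 25 S phase genes fell (median log2 change -1.73, adjusted p = 3.68e-12, adjusted p = 0.235 with an estimated correlation). Rrm1, the large subunit of ribonucleotide reductase, stood at 2995 ± 235 against 18799 ± 267, and cyclin D1 (Ccnd1) at 11432 ± 1363 against 51749.8 ± 2122. In G2 and M phase 1 rose, 22 fell and 2 did not pass (median log2 change -1.06, adjusted p = 1.01e-07, adjusted p = 0.380 with an estimated correlation). Ccna2 stood at 1891 ± 192 against 7465 ± 135. In cholesterol synthesis 2 rose, 22 fell and 1 did not pass (median log2 change -1.26, adjusted p = 1.08e-08, adjusted p = 0.163 with an estimated correlation): Nsdhl, a sterol dehydrogenase, stood at 371 ± 12.6 against 3702 ± 10.4, while Pcsk9, which directs the LDL receptor to degradation, rose to 219 ± 16.0 against 4.78 ± 1.59. NRF2 targets fell in 18 of 22 and rose in 4 (median log2 change -1.13, adjusted p = 6.44e-05, adjusted p = 0.163 with an estimated correlation). Osgin1 stood at 699 ± 51.4 against 8719.5 ± 141 and the glutathione transferase Gsta3 at 5492 ± 160.3 against 483 ± 25.8. In the YAP target list 4 rose, 12 fell and 4 did not pass (median log2 change -0.39, adjusted p = 0.0136, adjusted p = 0.438 with an estimated correlation). The matricellular gene Ccn2 stood at 318 ± 11.2 against 61866 ± 91.6 and the receptor kinase Axl at 8635 ± 54.4 against 905 ± 47.7. In the H3K4 methylation machinery 6 rose, 13 fell and 5 did not pass (median log2 change -0.35, adjusted p = 0.0468, adjusted p = 0.506 with an estimated correlation). The demethylase Kdm1a stood at 309.9 ± 19.7 against 2493 ± 83.4.

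Among single genes in TP against TY, the receptor gene Cd244a was at least 3022-fold higher, the Wnt antagonist Dkk2 at least 2116-fold and the matrix gene Thbs2 at least 1620-fold. Fstl1, which encodes a secreted glycoprotein, was 6368-fold (95% counting interval 3354 to 13927) higher. Psca, a surface antigen of gastric epithelium, was 2553-fold (95% counting interval 873 to 12384) lower, the ligand Wnt7a 2083-fold (95% counting interval 576 to 17205) lower and Gpa33, an intestinal cell surface antigen, 927-fold (95% counting interval 397 to 2857) lower. In all, 12815 genes passed, 7627 higher and 5188 lower in TP, and 6721 of them changed at least 2-fold. The split was 6807 and 5963 with DESeq2 size factors, 6769 and 6008 with TMM and 7446 and 5340 with upper quartiles. The median of all genes was 0.24 with the deposited scaling and 0.07 with TMM, so each change stands against that shift. The lists without a set-test call were gastric pit (4 rose and 5 fell of 10, adjusted p = 0.412), mucous neck and SPEM (8 and 3 of 12, adjusted p = 0.452), parietal (3 and 6 of 9, adjusted p = 0.132) and enteroendocrine cell (4 and 0 of 6, adjusted p = 0.473). The same held for tuft cell (5 and 2 of 8, adjusted p = 0.452), Wnt (13 and 7 of 20, adjusted p = 0.412), squamous (5 and 6 of 15, adjusted p = 0.452), immune (4 and 3 of 8, adjusted p = 0.946) and FOXO targets (9 and 8 of 23, adjusted p = 0.555). Nor were fatty acid synthesis (6 and 10 of 18, adjusted p = 0.324), ribosome biogenesis (20 and 7 of 30, adjusted p = 0.140), lysosome (16 and 17 of 37, adjusted p = 0.392) and mTOR components (18 and 22 of 44, adjusted p = 0.324) called. The last were p53 targets (8 and 10 of 20, adjusted p = 0.204), ERK feedback (14 and 5 of 22, adjusted p = 0.111) and unfolded protein response (14 and 4 of 21, adjusted p = 0.111). Of the 4 tested chief cell genes 3 rose and 1 fell, too few for a set test. The counts adjusted over the list alone were as above except in mesenchymal transition (4 fell) and enteroendocrine cell (3 rose). Median, mean and test differed in sign for uncalled lists: gastric pit, squamous, immune, FOXO, fatty acid, lysosome, mTOR and p53. The H3K4 call was lost without the first TP DMSO library (adjusted p = 0.0919) or the second TY DMSO library (0.0587). The calls of the endothelial and intestinal lists were lost without the second TP DMSO library (0.0534 and 0.0526), and that of the endothelial list with the replicate block (0.0510).

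The comparison of TPCD with TP in DMSO asks what differs in the cells that also carry floxed Kmt2c and Kmt2d. Other differences between the cultures, such as those in Xist and in chromosome medians given below, cannot be told apart from the floxed genes. All 20 epithelial identity genes rose in the libraries labelled TPCD (median log2 change 3.19, adjusted p = 8.42e-15). Ap1m2 stood at 3739 ± 9.95 against 8.43 ± 2.16, Rab25 at 5312 ± 173 against 24.2 ± 3.57 and Cldn4 at 14983 ± 275 against 109 ± 21.7. All 22 NRF2 targets rose (median log2 change 2.47, adjusted p = 9.56e-16). The glutathione transferase Gsta1 stood at 16282 ± 138 against 23.9 ± 4.55 and the quinone reductase Nqo1 at 24479.6 ± 175 against 331 ± 46.6. These calls held with an estimated correlation (adjusted p = 0.0340 for the epithelial list and adjusted p = 0.0346 for NRF2). Mesenchymal transition genes fell in 18 of 19 (median log2 change -5.76, adjusted p = 0.000230, adjusted p = 0.108 with an estimated correlation), or a median of -5.68 at the bound. Mmp14, a membrane-bound matrix metalloproteinase, fell to 1 read, a ratio of 6726-fold (95% counting interval 1207 to 265699), and the fibrillin gene Fbn1 was 162-fold (95% counting interval 106 to 262) lower. Among fibroblast genes 6 of 8 fell, with no call for the list (adjusted p = 0.0534).

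Proliferation and sterol genes were higher in TPCD than in TP. All 25 S phase genes rose (median log2 change 1.88, adjusted p = 8.42e-15, adjusted p = 0.197 with an estimated correlation). The helicase subunit Mcm3 stood at 6576 ± 53.2 against 1099 ± 46.6. In G2 and M phase 22 rose, 0 fell and 3 did not pass (median log2 change 1.14, adjusted p = 6.23e-11, adjusted p = 0.314 with an estimated correlation). The ubiquitin-conjugating enzyme Ube2c stood at 9283 ± 392 against 2177 ± 97.5. In cholesterol synthesis 22 of 25 rose and 3 fell (median log2 change 0.86, adjusted p = 2.95e-09, adjusted p = 0.164 with an estimated correlation). Acat2 stood at 3391 ± 145 against 621 ± 21.2. In fatty acid synthesis 11 rose, 6 fell and 1 did not pass (median log2 change 0.45, adjusted p = 0.0144, adjusted p = 0.314 with an estimated correlation). The desaturase Scd2 stood at 118024 ± 4665 against 31582 ± 460.3. NF-kB and chemokine genes fell in 21 of 25 and rose in 4 (median log2 change -3.80, adjusted p = 5.67e-05, adjusted p = 0.164 with an estimated correlation): the neutrophil attractant Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115) stood at 15.8 ± 4.20 against 137593 ± 154 and Ccl2 was 8238-fold (95% counting interval 5334 to 13487) lower. ATF4 and amino acid genes fell in 28, rose in 2 and did not pass in 2 (median log2 change -1.28, adjusted p = 3.34e-05, adjusted p = 0.164 with an estimated correlation). The cationic amino acid transporter Slc7a3 stood at 46.9 ± 11.97 against 1759.8 ± 1.09. In the interferon response 21 rose, 6 fell and 4 did not pass (median log2 change 1.04, adjusted p = 0.000157, adjusted p = 0.164 with an estimated correlation). Oasl1 stood at 11069.7 ± 325 against 1116 ± 0.331. In antigen presentation 10 rose, 3 fell and 5 did not pass (median log2 change 0.79, adjusted p = 0.00696, adjusted p = 0.453 with an estimated correlation). The class II chaperone Cd74 stood at 14.9 ± 6.64 against 505 ± 21.9 and the immunoproteasome subunit Psmb9 at 1318 ± 56.5 against 449 ± 23.2. In ribosome biogenesis 2 rose, 24 fell and 4 did not pass (median log2 change -0.47, adjusted p = 0.0144, adjusted p = 0.637 with an estimated correlation). Rrp12 stood at 749 ± 31.0 against 2563 ± 51.0. The ribosome call was lost with DESeq2 size factors (median -0.22, adjusted p = 0.133).

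Further single genes that rose in TPCD against TP were Gsta2 at 10316 ± 297 against 6.19 ± 0.206 and the chloride channel regulator Clca3b at 36669 ± 1640.3 against 143 ± 9.13. The galectin gene Lgals1 was 3797-fold (95% counting interval 2220.3 to 7132) lower, the scavenger receptor gene Scara5 12180.0-fold (95% counting interval 4167 to 59065) lower and the tight junction gene Cldn2 11651-fold (95% counting interval 2091 to 460245) lower. A total of 12602 genes passed, 4492 higher and 8110 lower, and 6510 changed at least 2-fold. The share of calls that were higher depended on the scaling: 35.6% as deposited, 46.6% with DESeq2 size factors, 46.9% with TMM and 44.5% with upper quartiles, while the median of all genes moved from -0.33 to -0.07 with TMM. Every called list kept its counts when adjusted over the list alone. Median, mean and test differed in sign for the uncalled lists gastric pit, parietal cell, squamous, glycolysis, p53 and H3K4, and the uncalled lists had adjusted p from 0.0534 to 0.974.

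The comparison of TPCD with the TY control in DMSO asks what differs in the cells that carry all the floxed genes. Here too genotype and culture cannot be told apart. All 31 interferon response genes rose (median log2 change 6.12, adjusted p = 1.20e-16), a call that held with an estimated correlation (adjusted p = 0.0362). Oasl1 stood at 11069.7 ± 325 in TPCD and 2.35 ± 0.547 in TY. NRF2 targets rose in 21 of 22 and fell in 1 (median log2 change 2.12, adjusted p = 9.16e-11, adjusted p = 0.0931 with an estimated correlation). Gsta2 stood at 10316 ± 297 against 51.1 ± 18.1. Genes of glycolysis and HIF rose in 26 of 28 and fell in 2 (median log2 change 1.25, adjusted p = 7.09e-09, adjusted p = 0.450 with an estimated correlation). The HIF hydroxylase Egln3 stood at 9854 ± 987 against 728 ± 17.1. In antigen presentation 16 rose, 1 fell and 1 did not pass (median log2 change 2.82, adjusted p = 3.85e-07, adjusted p = 0.392 with an estimated correlation, or a median of 2.59 at the bound). YAP targets fell in 16 of 20 and rose in 4 (median log2 change -1.39, adjusted p = 0.00128, adjusted p = 0.450 with an estimated correlation). Ccn2 stood at 2709 ± 203 against 61866 ± 91.6. In fatty acid synthesis 11 rose, 2 fell and 5 did not pass (median log2 change 0.27, adjusted p = 0.0266, adjusted p = 0.450 with an estimated correlation). Epithelial identity had no call (8 rose, 10 fell and 2 did not pass, adjusted p = 0.981), nor had S phase (adjusted p = 0.426) or G2 and M phase (adjusted p = 0.317). These counts did not move when adjusted over the list alone. In all 11570 genes passed, 5356 higher and 6214 lower, with 5017 changed at least 2-fold. The majority turned with the scaling, to 5936 higher and 5648 lower with DESeq2 size factors, 5938 and 5646 with TMM and 6377 and 5233 with upper quartiles, and the median of all genes moved from -0.05 to 0.08 with upper-quartile scaling. Median, mean and test differed in sign for the uncalled lists gastric pit, epithelial identity, cholesterol, immune and ERK feedback.

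The median change also differed between chromosomes. In TP against TY in DMSO the median log2 change, less that of all autosomal genes, was 0.63 on chromosome 1, 0.40 on 4, 0.55 on 11, 0.69 on 14 and 0.42 on 17. In TPCD against TY it was 0.36, 0.44, 0.51, 0.49 and 0.83 on these, and -0.41, -0.46 and -0.45 on 7, 8 and 9. The 19 autosomal medians correlated between DMSO and rapamycin with r of 0.994 and 0.998, across chromosomes, which are not independent replicates. For TPCD against TP in DMSO, the median less that of all autosomal genes was 0.51 on chromosome 15, which holds Kmt2d. It was -0.35 on chromosome 5, which holds Kmt2c, and 0.15 on chromosome 19, which holds Pten. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), the RNA that coats the inactive X, lay between 60103 and 90763 in the TY and TP libraries. In the libraries labelled TPCD it lay at 3.42, 9.82, 3.63 and 119, and genes of the Y chromosome had at most 3 reads in any library.

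**Figure D2:**
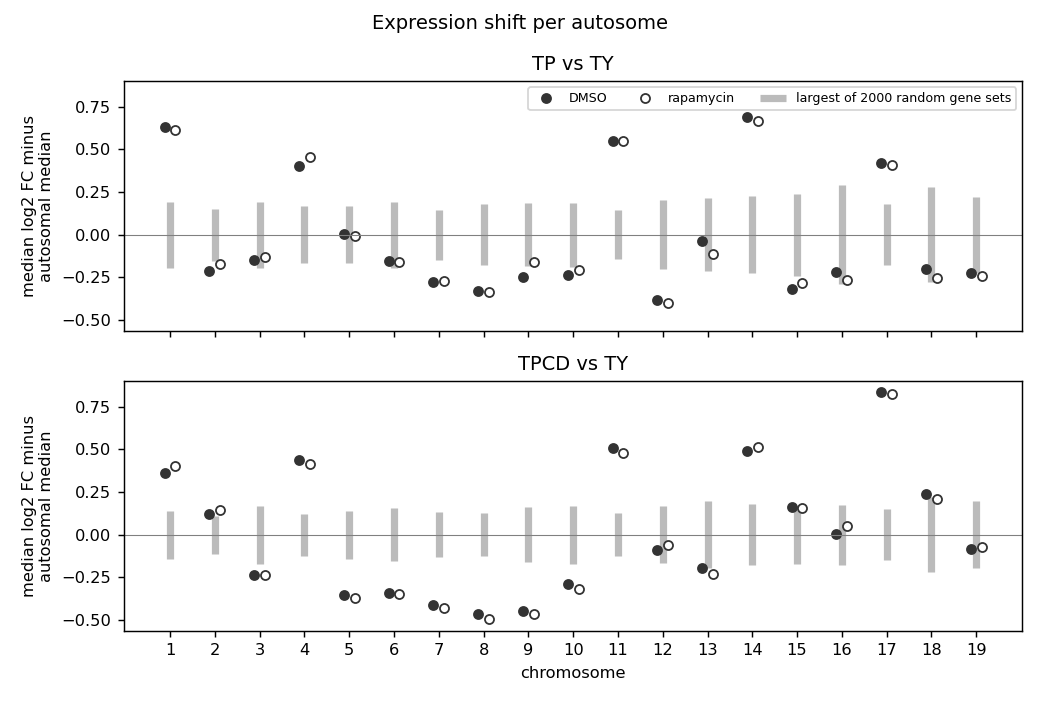
Median log2 change of each autosome less that of all autosomal genes, for TP against TY and TPCD against TY, with DMSO filled, rapamycin open and the largest of 2000 random gene sets of the same size in grey. Chromosome 17 lay at 0.83 in TPCD against TY and chromosome 14 at 0.69 in TP against TY, both in DMSO.

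Rapamycin against DMSO in TY cells gives the response of the control. All 25 G2 and M phase genes fell (median log2 change -0.81, adjusted p = 1.61e-20, adjusted p = 0.192 with an estimated correlation). The mitotic kinase Plk1 stood at 2226 ± 227 against 4548 ± 78.4 and the anaphase activator Cdc20 at 1324 ± 112 against 2776 ± 59.9. ATF4 and amino acid genes fell in 25 of 32 and rose in 1 (median log2 change -0.87, adjusted p = 5.94e-18), a call that held with an estimated correlation (adjusted p = 0.0290). Aldh1l2 stood at 33.1 ± 9.84 against 192 ± 7.43, the pseudokinase gene Trib3 at 184 ± 11.7 against 655 ± 84.4 and Cth, a transsulfuration enzyme, at 326 ± 26.6 against 939 ± 54.2. In cholesterol synthesis 0 rose, 24 fell and 1 did not pass (median log2 change -0.57, adjusted p = 8.34e-16, adjusted p = 0.0807 with an estimated correlation). Lanosterol synthase (Lss) stood at 2189.8 ± 90.2 against 3919 ± 143. In fatty acid synthesis 0 rose, 17 fell and 1 did not pass (median log2 change -0.52, adjusted p = 5.49e-11, adjusted p = 0.0654 with an estimated correlation). The desaturase Scd1 stood at 141 ± 6.91 against 488 ± 14.8. In the NRF2 target list 2 rose, 18 fell and 2 did not pass (median log2 change -0.69, adjusted p = 1.82e-09, adjusted p = 0.0807 with an estimated correlation). The cystine transporter Slc7a11 stood at 3363 ± 129 against 7617 ± 648. Of the unfolded protein response genes 2 rose, 14 fell and 5 did not pass (median log2 change -0.22, adjusted p = 0.000289, adjusted p = 0.322 with an estimated correlation). The chaperone Hsp90b1 stood at 25918 ± 795 against 38714 ± 25.5.

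Set tests called the ERK, YAP and FOXO target lists higher in TY with rapamycin, and p53 targets and glycolysis genes lower. Many members of these lists did not pass, and none of these calls held with an estimated correlation. In ERK feedback and immediate early genes 10 rose, 1 fell and 11 did not pass (median log2 change 0.18, adjusted p = 1.26e-06, adjusted p = 0.224 with an estimated correlation). Myc stood at 6791 ± 206 against 3553 ± 51.5 and the ERK phosphatase Dusp6 at 5759 ± 317 against 3065 ± 102. In the YAP target list 10 rose, 1 fell and 9 did not pass (median log2 change 0.35, adjusted p = 2.79e-06, adjusted p = 0.219 with an estimated correlation). Ccn2 stood at 101827 ± 3554 against 61866 ± 91.6. In the FOXO target list 8 rose, 5 fell and 10 did not pass (median log2 change 0.15, adjusted p = 0.00883, adjusted p = 0.322 with an estimated correlation). The ubiquitin ligase Fbxo32 stood at 562 ± 3.03 against 241 ± 0.194 and the insulin receptor substrate Irs2 at 1629 ± 36.3 against 861 ± 52.1. In NF-kB and chemokine genes 8 rose, 3 fell and 14 did not pass (median log2 change 0.14, adjusted p = 0.0122, adjusted p = 0.322 with an estimated correlation, or a median of 0.15 at the bound). Ptgs2 stood at 1589 ± 169 against 926 ± 33.4. Of p53 targets 0 rose, 11 fell and 9 did not pass (median log2 change -0.16, adjusted p = 0.00104, adjusted p = 0.103 with an estimated correlation). Ccng1 stood at 13773 ± 199.9 against 18029 ± 306. Of glycolysis and HIF genes 0 rose, 12 fell and 16 did not pass (median log2 change -0.20, adjusted p = 0.00316, adjusted p = 0.746 with an estimated correlation). The phosphofructokinase Pfkp stood at 2397 ± 8.93 against 4562 ± 168. Further single genes that rose were the granule protease Mcpt8 at 5381 ± 181 against 1341 ± 87.6 and the chemokine Ppbp at 1074 ± 29.8 against 351 ± 5.85. In all 4615 genes passed and 389 of them changed at least 2-fold. Of the calls 28.7% were higher as deposited, 50.7% with DESeq2 size factors, 50.8% with TMM and 48.9% with upper quartiles. Adjusted over the list alone, 25 cholesterol and 27 ATF4 genes fell, 10 FOXO, 9 NF-kB, 11 YAP and 11 ERK genes rose, and 15 unfolded protein response, 4 NF-kB and 2 ERK genes fell, and 1 p53 target rose. The FOXO call was lost without the first TY rapamycin library (adjusted p = 0.0591), and the NF-kB call without the second TY DMSO library (adjusted p = 0.190). The uncalled lists had adjusted p from 0.0689 (mTOR components) upward, and median, mean and test differed in sign for pit, neck, parietal, enteroendocrine, S phase and antigen presentation genes.

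In TP cells rapamycin was followed by rises of the proliferation and sterol genes that lay low in DMSO. The same 2 TP DMSO libraries enter this comparison and those of TP with TY and of TPCD with TP in DMSO. The rises here and the differences there are therefore not independent findings. Of S phase genes 24 rose, 0 fell and 1 did not pass (median log2 change 1.44, adjusted p = 2.78e-19, adjusted p = 0.219 with an estimated correlation). The helicase subunit Mcm3 stood at 4599 ± 113 against 1099 ± 46.6 and Mcm7 at 12332 ± 239 against 3357 ± 185. All 25 G2 and M phase genes rose (median log2 change 0.80, adjusted p = 2.08e-14, adjusted p = 0.274 with an estimated correlation). Cyclin A2 (Ccna2) stood at 5806 ± 119 against 1891 ± 192 and topoisomerase II alpha (Top2a) at 38157 ± 46.2 against 13324 ± 1629. In cholesterol synthesis 20 rose, 4 fell and 1 did not pass (median log2 change 0.71, adjusted p = 2.18e-10, adjusted p = 0.203 with an estimated correlation). Acat2 stood at 2199 ± 116 against 621 ± 21.2. In fatty acid synthesis 14 rose, 2 fell and 2 did not pass (median log2 change 0.37, adjusted p = 1.00e-05, adjusted p = 0.203 with an estimated correlation). Acsl3, which activates long-chain fatty acids, stood at 6549 ± 134 against 1784 ± 161. All 32 ATF4 and amino acid genes fell (median log2 change -2.69, adjusted p = 2.78e-19), a call that held with an estimated correlation (adjusted p = 0.0239). Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032) stood at 119 ± 3.06 against 14121 ± 489.8, the glutathione-degrading enzyme Chac1 at 55.1 ± 6.08 against 4889 ± 593 and Atf3 at 82.7 ± 0.962 against 4621 ± 133.

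Ribosome biogenesis and immediate early genes fell in TP. In ribosome biogenesis 2 rose, 28 fell and 0 did not pass (median log2 change -0.91, adjusted p = 1.69e-08, adjusted p = 0.274 with an estimated correlation). Rrp12 stood at 726 ± 2.07 against 2563 ± 51.0 and Nip7 at 1126 ± 31.4 against 3243 ± 149.5. Of ERK feedback and immediate early genes 2 rose, 17 fell and 3 did not pass (median log2 change -0.98, adjusted p = 0.000143, adjusted p = 0.376 with an estimated correlation). The transcription factor Egr1 stood at 1129 ± 31.7 against 26993 ± 3339 and Junb at 2239 ± 119 against 21033 ± 944. Of NF-kB and chemokine genes 1 rose, 18 fell and 6 did not pass (median log2 change -0.74, adjusted p = 0.000296, adjusted p = 0.268 with an estimated correlation). The cytokine Il6 stood at 76.8 ± 3.93 against 3249 ± 64.9 and the cyclooxygenase Ptgs2 at 6236 ± 376 against 39625 ± 368. Of p53 targets 1 rose, 14 fell and 5 did not pass (median log2 change -0.58, adjusted p = 0.00189, adjusted p = 0.203 with an estimated correlation). The cell cycle inhibitor Cdkn1a stood at 3672 ± 46.0 against 10902 ± 308. Single genes that rose were mt-Nd2, a mitochondrially encoded subunit of complex I, at 102690.0 ± 1513 against 15475 ± 64.8, the retinol dehydrogenase Rdh10 at 18196 ± 147 against 3008 ± 129 and Fam107a at 586 ± 10.4 against 74.5 ± 11.9, while Gdf15, a stress-induced cytokine, fell to 362 ± 39.6 against 7010.0 ± 575. A total of 9934 genes passed, 3561 higher and 6373 lower, and 2979 changed at least 2-fold. Of the calls 35.8% were higher as deposited, 49.2% with DESeq2 size factors, 49.4% with TMM and 46.5% with upper quartiles, and the median of all genes moved from -0.18 to -0.02 with TMM. The called lists kept these counts adjusted over the list alone. Epithelial identity (9 rose, 8 fell and 3 did not pass, adjusted p = 0.666) and mesenchymal transition (1 rose, 8 fell and 10 did not pass, adjusted p = 0.367) had no call, and of the endothelial genes 1 rose, 5 fell and 0 did not pass (adjusted p = 0.426). Median, mean and test differed in sign for the uncalled lists FOXO, intestinal metaplasia, tuft, Wnt, epithelial, fibroblast, immune, antigen presentation, mTOR, NRF2, unfolded protein response and H3K4.

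In the libraries labelled TPCD the response to rapamycin included sterol, amino acid and inflammatory genes. All 25 cholesterol synthesis genes fell (median log2 change -0.55, adjusted p = 2.11e-18, adjusted p = 0.0535 with an estimated correlation). Pmvk stood at 586 ± 17.5 against 1418 ± 10.8 and Dhcr7, the last reductase of the pathway, at 1094 ± 32.7 against 2014 ± 95.01. In fatty acid synthesis 0 rose, 15 fell and 3 did not pass (median log2 change -0.43, adjusted p = 6.58e-10, adjusted p = 0.0535 with an estimated correlation). Scd1 stood at 2068 ± 152 against 7962 ± 390.1. Of ATF4 and amino acid genes 2 rose, 23 fell and 7 did not pass (median log2 change -0.60, adjusted p = 8.76e-13, adjusted p = 0.0535 with an estimated correlation). Trib3 stood at 836 ± 28.4 against 2419 ± 60.1 and Chac1 at 432 ± 14.0 against 1060.3 ± 67.8. Of NF-kB and chemokine genes 17 rose, 0 fell and 8 did not pass (median log2 change 0.60, adjusted p = 8.76e-13, adjusted p = 0.0535 with an estimated correlation). The chemokine Ccl20 stood at 299 ± 13.9 against 69.7 ± 6.44 and the growth factor Csf2 at 58.6 ± 1.95 against 14.3 ± 3.87. Unfolded protein response genes fell in 16 of 21 and rose in 1 (median log2 change -0.36, adjusted p = 2.10e-09, adjusted p = 0.144 with an estimated correlation). The chaperone Hspa5 stood at 30821 ± 182 against 47727 ± 2107. In the NRF2 target list 2 rose, 16 fell and 4 did not pass (median log2 change -0.36, adjusted p = 1.35e-08, adjusted p = 0.0714 with an estimated correlation). Heme oxygenase (Hmox1) stood at 3842 ± 154 against 6548 ± 184. Of glycolysis and HIF genes 2 rose, 20 fell and 6 did not pass (median log2 change -0.40, adjusted p = 5.92e-08, adjusted p = 0.409 with an estimated correlation). Egln3 stood at 5726 ± 26.5 against 9854 ± 987.

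Among groups that rose in TPCD were YAP targets, of which 12 rose, 1 fell and 7 did not pass (median log2 change 0.31, adjusted p = 1.83e-06, adjusted p = 0.185 with an estimated correlation). Ccn2 stood at 6265 ± 41.4 against 2709 ± 203 and Amotl2 at 8238 ± 179.8 against 4435 ± 73.3. Of ERK feedback and immediate early genes 12 rose, 1 fell and 9 did not pass (median log2 change 0.23, adjusted p = 2.34e-06, adjusted p = 0.225 with an estimated correlation). Dusp6 stood at 5150.2 ± 169 against 2999 ± 44.9. Of Wnt target and stem cell genes 9 rose, 2 fell and 9 did not pass (median log2 change 0.18, adjusted p = 0.000292, adjusted p = 0.135 with an estimated correlation). The stem cell receptor Lgr5 stood at 3119.7 ± 35.5 against 1639 ± 108 and the feedback gene Axin2 at 1184 ± 10.3 against 741 ± 24.8. Of FOXO targets 9 rose, 4 fell and 10 did not pass (median log2 change 0.11, adjusted p = 0.00684, adjusted p = 0.330 with an estimated correlation). Fbxo32 stood at 232 ± 16.1 against 66.4 ± 22.0 and the mTORC2 subunit Rictor at 4788 ± 301 against 2724 ± 69.0. The collagenase Mmp13 rose to 178 ± 9.47 against 24.1 ± 5.08 and the chitinase-like gene Chil1 to 496 ± 0.639 against 136 ± 34.6. S phase (2 rose, 0 fell and 23 did not pass, adjusted p = 0.446) and G2 and M phase (0 rose, 5 fell and 20 did not pass, adjusted p = 0.533) had no call. In all 4363 genes passed and 427 of them changed at least 2-fold, but 2535 passed without the second TPCD DMSO library and 2585 without the first TPCD rapamycin library. Of the calls 39.7% were higher as deposited, 48.8% with DESeq2 size factors, 51.1% with TMM and 49.3% with upper quartiles. Adjusted over the list alone, 24 ATF4, 22 glycolysis, 17 NRF2 and 18 unfolded protein response genes fell, 13 YAP, 10 FOXO and 10 Wnt genes rose, and 5 FOXO genes fell. Median, mean and test differed in sign for the uncalled parietal, enteroendocrine, tuft, squamous, immune, endothelial, interferon, H3K4, antigen presentation and S phase lists.

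**Figure D3:**
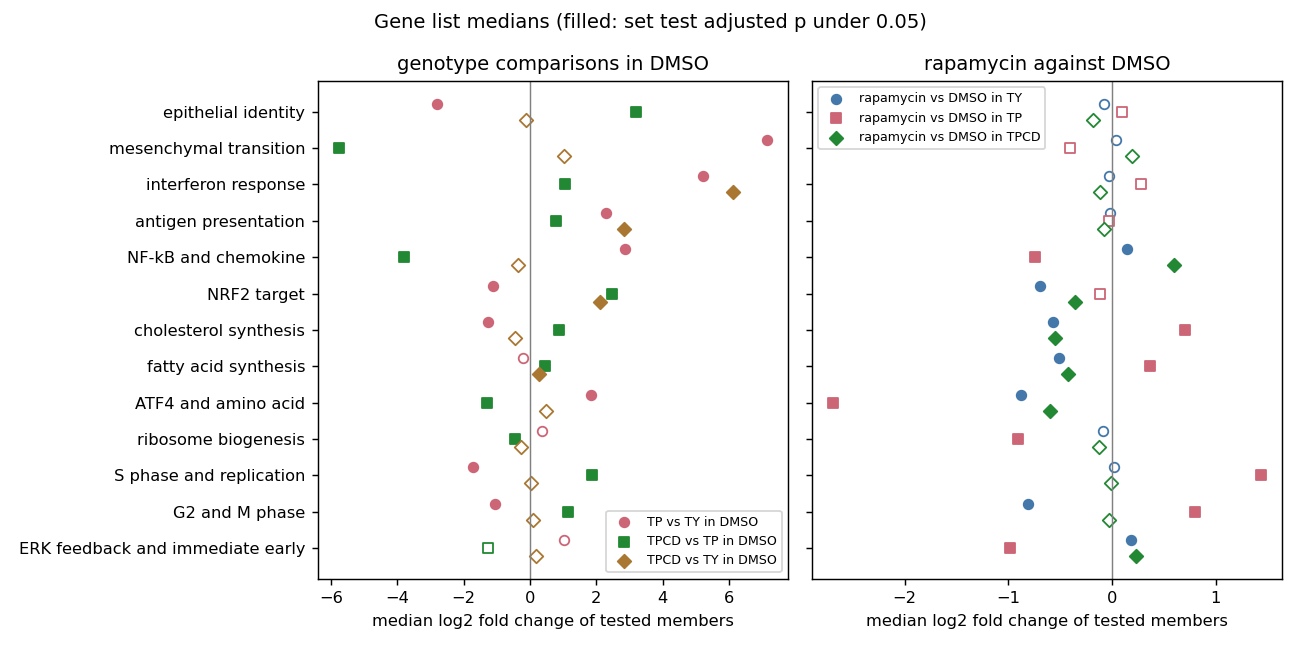
Median log2 change of the tested members of 13 gene lists, in the 3 genotype comparisons in DMSO on the left and for rapamycin against DMSO in each genotype on the right, filled where the set test had an adjusted p under 0.05. G2 and M phase genes had medians of -0.81 in TY, 0.80 in TP and -0.03 in TPCD with rapamycin.

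Whether rapamycin acted differently in the genotypes was tested as the difference between the responses. Both differences that involve TP contain the same TP DMSO and TP rapamycin libraries, so they are not independent of each other. Against TY, the response of TP was higher for all 25 G2 and M phase genes (median log2 change 1.58, adjusted p = 6.22e-20, adjusted p = 0.202 with an estimated correlation) and all 25 S phase genes (median log2 change 1.51, adjusted p = 1.01e-18, adjusted p = 0.202 with an estimated correlation). It was also higher for 23 of 25 cholesterol genes (median log2 change 1.34, adjusted p = 9.96e-17, adjusted p = 0.0962 with an estimated correlation) and 15 of 18 fatty acid genes (median log2 change 0.93, adjusted p = 2.08e-10, adjusted p = 0.0767 with an estimated correlation). It was lower for all 32 ATF4 and amino acid genes (median -1.62, adjusted p = 3.41e-18), which held with an estimated correlation (adjusted p = 0.0288). Ribosome biogenesis (1 higher, 27 lower, median log2 change -0.77, adjusted p = 3.31e-09, adjusted p = 0.214 with an estimated correlation), ERK feedback (2 and 18, median log2 change -1.36, adjusted p = 1.30e-07, adjusted p = 0.202 with an estimated correlation) and NF-kB genes (1 and 18, median log2 change -1.04, adjusted p = 1.10e-05, adjusted p = 0.202 with an estimated correlation) were lower too. The interaction term of Egr1 was -4.97, of Trib3 -5.06, of Ccna2 2.47 and of mt-Nd2 2.59. NRF2 targets were called higher (13 and 5, median log2 change 0.55, adjusted p = 0.00165, adjusted p = 0.249 with an estimated correlation), while YAP targets (3 and 14, median log2 change -0.50, adjusted p = 0.00469, adjusted p = 0.436 with an estimated correlation) and p53 targets (4 and 11, median log2 change -0.57, adjusted p = 0.0450, adjusted p = 0.243 with an estimated correlation) were called lower. The p53 call was lost with DESeq2 size factors (adjusted p = 0.0509) and without the second TY rapamycin library (0.0557), the first TP DMSO library (0.0550) or the first TP rapamycin library (0.0775). In all 8146 genes passed, 3411 higher and 4735 lower, and 2852 of them with a difference of at least 2-fold. The share that was higher, 41.9% as deposited, was 48.8% with DESeq2 size factors, 48.9% with TMM and 46.3% with upper quartiles, and DESeq2 on the recovered reads gave 3623 higher and 3619 lower.

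Against TP, the response of TPCD was higher for all 32 ATF4 and amino acid genes (median 2.12, adjusted p = 2.26e-19), which held with an estimated correlation (adjusted p = 0.0227). It was higher for all 25 NF-kB and chemokine genes (median log2 change 1.60, adjusted p = 2.94e-10, adjusted p = 0.0532 with an estimated correlation), 20 of 22 ERK feedback genes (median log2 change 1.26, adjusted p = 8.58e-09, adjusted p = 0.160 with an estimated correlation) and 26 of 30 ribosome biogenesis genes (median log2 change 0.85, adjusted p = 6.50e-09, adjusted p = 0.229 with an estimated correlation). It was lower for 24 of 25 S phase genes (median log2 change -1.52, adjusted p = 2.62e-19, adjusted p = 0.160 with an estimated correlation), 22 of 25 G2 and M phase genes (median log2 change -0.84, adjusted p = 1.32e-14, adjusted p = 0.242 with an estimated correlation), 23 of 25 cholesterol genes (median log2 change -1.30, adjusted p = 2.56e-19, adjusted p = 0.0532 with an estimated correlation) and 15 of 18 fatty acid genes (median log2 change -1.005, adjusted p = 4.15e-10, adjusted p = 0.0532 with an estimated correlation). The interaction term of Trib3 was 5.35, of Egr1 4.80, of Mmp13 4.92 and of Acat2 -2.61. YAP (14 higher and 1 lower, median log2 change 0.65, adjusted p = 0.000339, adjusted p = 0.322 with an estimated correlation) and p53 targets (13 and 3, median log2 change 0.74, adjusted p = 0.00198, adjusted p = 0.130 with an estimated correlation) were called higher. Unfolded protein response (3 and 10, median log2 change -0.39, adjusted p = 0.00198, adjusted p = 0.448 with an estimated correlation), NRF2 (5 and 12, median log2 change -0.30, adjusted p = 0.00766, adjusted p = 0.322 with an estimated correlation) and glycolysis genes (6 and 13, median log2 change -0.32, adjusted p = 0.0346, adjusted p = 0.835 with an estimated correlation) were called lower. The glycolysis call was lost without the second TP DMSO library (adjusted p = 0.138), the first TP rapamycin library (0.0742) or the first TPCD DMSO library (0.165). A total of 8110 genes passed, 4997 higher and 3113 lower, 2554 of them with a difference of at least 2-fold. Of the calls 61.6% were higher as deposited, 50.3% with DESeq2 size factors, 51.0% with TMM and 53.4% with upper quartiles. The majority turned on the recovered reads with DESeq2 (3583 higher and 3761 lower) and edgeR (3993 and 4102), but not with voom (4178 and 4128). The median of all genes moved from 0.14 to 0.02 with TMM.

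The responses of TPCD and TY differed at 1978 genes, 1332 higher and 646 lower, and 255 of them by at least 2-fold. All 25 G2 and M phase genes were higher (median log2 change 0.74, adjusted p = 6.83e-25, adjusted p = 0.268 with an estimated correlation). NF-kB genes were called higher (10 higher and 1 lower of 25, median log2 change 0.32, adjusted p = 5.19e-05, adjusted p = 0.268 with an estimated correlation), as were Wnt targets (8 and 1 of 20, median log2 change 0.35, adjusted p = 0.00227, adjusted p = 0.268 with an estimated correlation) and ATF4 and amino acid genes (13 and 3 of 32, median log2 change 0.23, adjusted p = 0.00227, adjusted p = 0.297 with an estimated correlation). The p53, unfolded protein response, NRF2 and H3K4 lists were also called, with adjusted p from 0.00241 to 0.0446 and from 0.268 to 0.726 with an estimated correlation. The number of differing genes was 1036 without the first TPCD rapamycin library, 1095 without the second TY DMSO library, 1147 without the second TY rapamycin library and 1175 without the second TPCD DMSO library. The share of calls that were higher was 67.3% as deposited, 52.2% with DESeq2 size factors, 54.9% with TMM and 55.2% with upper quartiles. TY and TPCD had 593 genes higher in both with rapamycin (146 expected from the sizes) and 1376 lower in both (551 expected). For TY and TP these were 523 (300.1 expected) and 1549 (1335 expected), but 463 genes were higher in TY and lower in TP (537 expected) and 945 the reverse (746 expected). TP and TPCD shared 622 (393 expected) and 1450 (1067 expected), with 552 higher in TP and lower in TPCD (596 expected) and 607 the reverse (703 expected). The expected numbers treat every gene as equally likely to be called, so an excess alone does not show a shared response. Genes called the same way numbered 2072 for TY and TP, 1969 for TY and TPCD and 2072 for TP and TPCD. With DESeq2 size factors they numbered 1585, 1626 and 1883. Without the second TPCD DMSO library TP and TPCD shared 1240 genes, and without the first TPCD rapamycin library 1310. Adjusted over the list alone, 15 YAP targets were lower in TP against TY. In TPCD against TP 24 cholesterol and 13 NRF2 targets were lower and 27 ribosome biogenesis genes higher. In TPCD against TY 13 NF-kB, 9 Wnt and 17 ATF4 genes were higher and 2, 2 and 4 lower. Across genes, which are not independent replicates, the genotype difference in rapamycin rose with that in DMSO with a slope of 0.814 for TPCD against TP and 0.852 for TP against TY.

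The genotypes were also compared within rapamycin. In TP against TY all 20 epithelial genes fell (median log2 change -2.72, adjusted p = 1.93e-11, adjusted p = 0.0501 with an estimated correlation) and all 31 interferon genes rose (median log2 change 5.50, adjusted p = 1.93e-11, adjusted p = 0.0501 with an estimated correlation). Genes of glycolysis and HIF rose in 27 of 28 (median log2 change 1.60, adjusted p = 4.79e-08, adjusted p = 0.414 with an estimated correlation), antigen presentation genes in 15 of 18 (median log2 change 2.05, adjusted p = 0.000124, adjusted p = 0.315 with an estimated correlation) and NF-kB genes in 19 of 25 with 5 lower (median log2 change 2.30, adjusted p = 0.00403, adjusted p = 0.332 with an estimated correlation). Ptgs2 stood at 6236 ± 376 in TP and 1589 ± 169 in TY. Mesenchymal genes rose in 14 of 19 and fell in 5 (median log2 change 5.76, adjusted p = 0.0180, adjusted p = 0.313 with an estimated correlation) and fibroblast genes in 8 of 8 (median log2 change 6.66, adjusted p = 0.00403, adjusted p = 0.150 with an estimated correlation, or a median of 5.55 at the bound). G2 and M phase genes, which were lower in DMSO, rose in 20 of 25 and fell in 2 (median log2 change 0.49, adjusted p = 0.00403, adjusted p = 0.555 with an estimated correlation), while S phase had no call (7 rose, 13 fell and 5 did not pass, adjusted p = 0.123) and neither had cholesterol synthesis (11 rose, 7 fell and 7 did not pass, adjusted p = 0.963). Ribosome biogenesis genes fell in 21 of 30 and rose in 5 (median log2 change -0.53, adjusted p = 0.00212, adjusted p = 0.455 with an estimated correlation). Fatty acid, YAP, p53, unfolded protein response and ERK lists were called too, with adjusted p from 0.00144 to 0.0180 and no call with an estimated correlation. In TPCD against TP all 22 NRF2 targets rose (median 2.73, adjusted p = 1.81e-15) and all 20 epithelial genes rose (median 2.83, adjusted p = 1.15e-13), and both held with an estimated correlation (adjusted p = 0.0362 for each). ATF4 and amino acid genes, lower in TPCD in DMSO, rose in 22 of 32 and fell in 6 (median log2 change 0.67, adjusted p = 5.09e-05, adjusted p = 0.169 with an estimated correlation, or a median of 0.65 at the bound). Trib3 stood at 836 ± 28.4 in TPCD and 119 ± 3.06 in TP. Of S phase genes 16 rose, 3 fell and 6 did not pass (median log2 change 0.42, adjusted p = 0.00160, adjusted p = 0.653 with an estimated correlation), and of NF-kB genes 5 rose, 17 fell and 3 did not pass (median log2 change -1.76, adjusted p = 0.00344, adjusted p = 0.295 with an estimated correlation). Interferon, p53, ribosome, unfolded protein response, ERK, G2 and M phase, mesenchymal, fibroblast and neck cell lists were called too, with adjusted p from 0.000162 to 0.0422 and no call with an estimated correlation. Adjusted over the list alone, the counts printed here for lists within rapamycin were the same. In all 12302 genes passed in TP against TY and 11582 in TPCD against TP, with 5927 and 5128 changed at least 2-fold, and the median of all genes in TPCD against TP moved from -0.16 to -0.03 with TMM.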

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

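The genes and lists in this and the next paragraph were brought up by a test of a difference between groups, namely the interaction term between the rapamycin responses of genotypes. The numbers of genes whose responses differed were 8146 for TP and TY, 8110 for TPCD and TP, and 1978 for TPCD and TY. For TP minus TY the median interaction term was 1.34 for cholesterol synthesis, 0.93 for fatty acid synthesis, 1.58 for G2 and M phase, -1.04 for NF-kB and chemokine and -1.36 for ERK feedback genes. For TPCD minus TP it was -1.30 for cholesterol synthesis, -1.005 for fatty acid synthesis, 1.60 for NF-kB and chemokine and 1.26 for ERK feedback genes. In each of these lists the responses of the compared genotypes had medians of opposite sign and both set tests passed.

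Among single genes, the log2 response of TP less that of TY was 4.26 for Ppp1r1b, 3.14 for Fam107a, 2.73 for Prelp, 2.62 for Acat2, 2.59 for mt-Nd2 and 2.47 for Ccna2. The Prelp call was lost with DESeq2 (adjusted p = 0.129) and edgeR (adjusted p = 0.144) on the recovered reads. For genes with a lower response in TP it was -5.46 for Atf3, -5.11 for Chac1, -5.06 for Trib3, -4.97 for Egr1, -4.92 for Ppp1r15a and -4.56 for Igfbp3. The response of TPCD less that of TP was 5.35 for Trib3, 5.15 for Chac1, 4.93 for Atf3, 4.92 for Mmp13, 4.80 for Egr1 and 4.43 for Ppp1r15a. It was -2.86 for Fam107a, -2.61 for Acat2, -2.45 for mt-Nd2, -2.42 for Ppp1r1b, -2.37 for Rdh10 and -2.30 for Ces1g, where Ces1g had 8 reads in TPCD DMSO and 0 in TPCD rapamycin, and its call was lost without the second TP DMSO library (adjusted p = 0.0567) or the first TPCD DMSO library (adjusted p = 0.0582). Of the targeted genes, Pten had 0.45 for TP minus TY and -0.30 for TPCD minus TP, and for the latter difference Kmt2c had 0.58 and Kmt2d 0.58. The Kmt2c call was lost with voom (0.46, adjusted p = 0.139) and edgeR (0.47, adjusted p = 0.101). It was also lost without the second TP DMSO library (adjusted p = 0.0837), the second TP rapamycin library (adjusted p = 0.0722), the second TPCD DMSO library (adjusted p = 0.0656) or the first TPCD rapamycin library (adjusted p = 0.0806).

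The 3 patterns below were noticed in the tables, and only the one on rapamycin in TP rests on interaction terms. Of their tests, those of fibroblasts, of scaling, of a stressed state and of a single X chromosome were chosen after the result was seen. The loss of epithelial and gain of mesenchymal and inflammatory transcripts in TP DMSO libraries was weighed first. Fibroblasts in place of epithelial cells would bring their abundant transcripts, but the highest of Col1a1, Col1a2, Col3a1 and Dcn stood at 467. That lay below the median tested gene at 859. The 20 epithelial genes fell unequally, 9 to under 10% of TY while 3 stayed over 50%. These values argue only against fibroblasts rich in those transcripts. Col5a1, also on the fibroblast list, had 11264 reads in TP DMSO against 12 in TY DMSO, so other mesenchymal cells stay open. Scaling to one total is argued against by the median of the epithelial list with TMM, -2.96. Of the 6721 genes changed at least 2-fold in TP, 55.2% passed the same way and 15.8% the other way in TPCD against TY in rapamycin, which shares no library with it. A difference of the TP cells besides the Pten deletion stays open, because whatever else sets the libraries labelled TPCD apart, their lower Kmt2c included, could lower that share alike, and the labels do not say how many cultures or animals stood behind each genotype.

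The next pattern was that rapamycin raised cell cycle and cholesterol genes in TP and not in TY or TPCD. An exchange of the DMSO and rapamycin labels of the TP libraries was tested on the 1969 genes called the same way in TY and TPCD, of which 64.5% had the same sign in TP as labelled, 52.9% were called the same way and 26.6% the other way. These values and the ATF4 list, whose medians were -0.87 in TY, -2.69 in TP and -0.60 in TPCD, run the way the labels say, but the first lies between the bounds of 25% and 75% written before it was seen and the sterol lists run the other way, so an exchange stays open. Scaling to one total is argued against by the median of the G2 and M phase list in TP with TMM, 0.96. A stressed or growth-arrested state of TP cells in DMSO may also underlie it, since the S phase list had a median of -1.73 against TY in DMSO, but an effect of the genotype would give the same value and so it stays open.

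The last pattern was the chromosome-wide shifts of expression and the low Xist RNA in the libraries labelled TPCD. X-linked genes active on both X chromosomes are argued against, since the other X-linked genes lay at -0.34 relative to autosomal genes in TPCD against TY, and so are trends on GC content, length and expression level, since chromosome 17 still lay 0.84 above the autosomal median once they were removed. Unequal numbers of chromosome copies in the cells of the genotypes may account for the shifts: on chromosomes 1, 4, 11, 14 and 17, which were picked by their raised medians in DMSO, 97.0% of 66 windows lay above the autosomal median in TPCD against TY in rapamycin, so the shift was spread along them, though this repeat in the same genotypes does not test whether they were raised and no DNA was measured. Cells with 1 X chromosome and no Y remain open. The median of the 5 genes that escape X inactivation lay at -0.50 relative to that of the other X-linked genes in TPCD against TY in DMSO. In TPCD against TP it lay at -0.25 in DMSO and -0.35 in rapamycin. The 5 genes did not move alike. In TPCD against TY, Eif2s3x, Kdm6a and Kdm5c lay below the median of the other X-linked genes (-0.42). Ddx3x (-0.29) and Pbdc1 (-0.27) lay above it, and the other X-linked genes had an SD of 1.65. In TPCD against TP the other X-linked genes lay at 0.06 and -0.10 relative to autosomal genes, as a single X would give. They lay at -0.34 in TPCD against TY, which is lower than a single X needs, and at -0.32 in TP against TY, where Xist was high.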

How the results depend on the processing

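With a minimum change of 2-fold, the counts of genes were 6721 (TP against TY), 6510 (TPCD against TP) and 5017 (TPCD against TY) in DMSO, 5927 and 5128 for the former 2 in rapamycin, and 389, 2979 and 427 for rapamycin in TY, TP and TPCD. They were 2852, 2554 and 255 for the differences of responses (TP minus TY, TPCD minus TP, TPCD minus TY), and 93, 64 and 118 for the overlaps of TY with TP, TY with TPCD and TP with TPCD. This follows from the added fold minimum.

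With each library left out in turn, so that the lone replicate is assumed to vary like the other groups, the counts ranged over 11831 to 12198, 11509 to 11869 and 10819 to 10874 for these genotype comparisons in DMSO and over 11505 to 11582 and 10636 to 10772 in rapamycin. For rapamycin they ranged over 3390 to 3726 in TY, 8435 to 8786 in TP and 2535 to 3319 in TPCD, and for the differences of responses over 7091 to 7636, 7019 to 7574 and 1036 to 2090. The overlaps ranged over 1487 to 1866, 1324 to 1693 and 1240 to 1897, and the slopes over 0.843 to 0.883 (TP against TY) and 0.805 to 0.842 (TPCD against TP). These fits have fewer samples by construction. Those for TPCD fell over 1.5-fold without its second DMSO library (2535) or first rapamycin library (2585), and the libraries behind the range of TPCD minus TY are named in the report.

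Directions turned for 4 results on the targeted genes. Pten in TPCD against TP in DMSO, -0.24 as deposited, was 0.0068 with DESeq2 size factors, 0.014 with TMM, 0.0065 with DESeq2, 0.017 with voom and 0.017 with edgeR, and -0.04 with upper quartiles. Kmt2d in that comparison, -0.03, was 0.22, 0.23 and 0.17 with size factors, TMM and upper quartiles, and 0.22, 0.23 and 0.23 with DESeq2, voom and edgeR, and -0.15 to 0.10 with a library left out. It was not called as deposited (adjusted p = 0.806) and was called higher in these settings (adjusted p from 0.0172 to 0.0297), except with upper quartiles (adjusted p = 0.0759) or a library left out (adjusted p from 0.181 to 0.902). Kmt2c in the response of TP minus TY, -0.02, was 0.051, 0.052 and 0.026, then 0.051, 0.057 and 0.054 under the same settings, and -0.19 to 0.14 with a library left out. Kmt2d with rapamycin in TY, -0.03, was 0.052, 0.052 and 0.045, then 0.052, 0.052 and 0.053, and -0.10 to 0.039 with a library left out. The scalings moved the median of all genes; beyond this the cause was not tested.

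The 84 called lists checked came from TP against TY and TPCD against TP in DMSO, rapamycin in each genotype, and the response differences TP minus TY and TPCD minus TP. Called lists of the other comparisons were not in these counts. With an estimated correlation only 6 of the 84 calls stayed and 78 were lost. Of the 684 values over all settings, 591 kept direction and call, and the other 93 were weaker. Of 4254 values for 260 results on named genes, 4232 kept both and 22 were weaker, and of 564 for 33 results on targeted genes 503 did. The named genes were picked mostly as the largest called changes in these data, a choice that favours keeping direction and call. With the replicate number as a block the overlaps were 2008, 1880 and 2015, yet the labels do not pair replicates, whose residuals correlated by -0.05 to 0.04 over 15 pairs of groups, across genes. Depth limited genes near 0 reads, whose folds are bounds or wide intervals.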

Other observations

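With the deposited scaling, a set of 1041 genes passed the same way with rapamycin in all 3 genotypes, 275 higher and 766 lower. Among those higher were Crebrf (1.31, 1.302 and 1.54), the complement proteases C1ra (1.25, 1.302 and 1.09) and C1s1 (1.04, 1.53 and 2.05), complement factor H, Cfh (0.75, 1.01 and 1.14), and ceruloplasmin, Cp (0.73, 0.81 and 0.85), with log2 changes in TY, TP and TPCD in that order. Among those lower were the amino acid transporters Slc7a5 (-1.30, -3.79 and -1.09) and Slc1a4 (-1.21, -3.18 and -0.86), asparagine synthetase, Asns (-1.08, -3.15 and -0.82), and the serine synthesis enzymes Psat1 (-1.11, -1.67 and -0.91) and Psph (-0.93, -2.67 and -0.89). These genes were picked by their size in these libraries. The split of the 1041 genes was not counted with other scalings. Of the rapamycin calls in TY, TP and TPCD, 28.7%, 35.8% and 39.7% were higher as deposited. With DESeq2 size factors these shares were 50.7%, 49.2% and 48.8%, so the excess of lower genes may follow the scaling.

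Across genes, which are not independent replicates, the rapamycin response correlated with the genotype difference in DMSO by -0.11 for TPCD against TP and -0.31 for TP against TY. Because both share the DMSO libraries, unchanged simulated groups were set beside them, and their mean correlation was -0.50, further from 0 than either. Noise of equal size in groups that share libraries gives that value whatever the data, so it does not weigh the observed correlations. The covariance was -0.10 for TPCD against TP and -0.67 for TP against TY, and -0.04 in the mean of 50 simulated draws.

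For each TPCD library, genes with at most 1 read over the other TPCD libraries and at least 500 on average in TP and TY were taken. Their reads amounted to 0.0905% (23 reads, 15 genes) and 0.0173% (3 reads, 12 genes) of their TP and TY level in the TPCD DMSO libraries. In the TPCD rapamycin libraries they amounted to 0.0338% (6 reads, 13 genes) and 0.231% (64 reads, 20 genes). The gene sets differed between libraries and the reads were few, so these shares are not comparable. In TPCD against TY in DMSO, the log2 change of the X-linked genes that escape inactivation was -1.58 for Eif2s3x, -1.07 for Kdm6a, -0.92 for Kdm5c, -0.29 for Ddx3x and -0.27 for Pbdc1. Ribosomal protein genes took 4.82%, 4.99% and 6.49% of the signal in TY, TP and TPCD with DMSO and 6.53%, 7.23% and 6.92% with rapamycin.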
